A study of Mus musculus with 8 samples.

How the data were processed

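RNA was sequenced from stomach of wild-type C57BL/6J mice and of mice lacking Lgals8, the gene for galectin-8, at 3 and 8 weeks of age. The 8 libraries form 4 groups of 2, named here by genotype (WT or KO), age and replicate number. Per the labels, total RNA was column-purified, polyadenylated RNA was selected, and fragments were read from both ends on a NovaSeq instrument. The labels do not state whether the replicates of a group are separate animals, so every p-value measures the spread between these samples.

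The authors deposited one table of raw counts per Ensembl gene, made with bcl2fastq, STAR 2.7.9a and featureCounts 2.0.3 from Subread on genome build GRCm38. The annotation release, the strand setting and the treatment of reads that match several genes are not given in the sources used here, so counts of near-identical gene copies and of overlapping genes on opposite strands are uncertain. The table held 40757 lines for 40481 gene IDs. The 276 repeated lines carried the same counts as their first copy and were left out, and 26 symbols that a spreadsheet had turned into dates were restored from the gene ID. Of the IDs, 40340 were found in GENCODE release M21, which is on the same build and gave the gene positions.

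Depth ran from 58851837 to 80686621 counts per library. Intervals and floors from counts cover counting error only. A group with 0 counts was given a floor of 3 counts per library, and a fold against it is a lower bound.

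Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with the group labels, which left 19647, and libraries were scaled by TMM. A quasi-likelihood model with 1 mean per group was fitted to all 8 libraries with robust dispersion estimates, leaving 4 residual degrees of freedom. 6 contrasts were tested: genotype at 3 weeks, genotype at 8 weeks, age in wild type, age in knockout, the difference between the 2 age effects (interaction), and the mean genotype effect over both ages. P-values were adjusted by Benjamini-Hochberg within a contrast with a threshold of 0.05, and "adjusted p" means that value from edgeR for a gene and from limma camera for a gene list. Levels are CPM after TMM scaling with the SD over n = 2 libraries, and changes are log2 fold changes with their SE.

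32 gene lists with 389 members were fixed before the data were examined, from textbook markers of cell types and processes; 376 members were tested. 31 lists were tested with camera in limma 3.58.1 on voom values with a preset inter-gene correlation of 0.01, and again with an estimated correlation. The list test fry of limma was also planned. For genotype at 3 weeks its adjusted p was 0.23 for the erythroid and cell cycle lists. At 8 weeks it was 0.068 for the chief and acinar lists, 0.17 for macrophages and granulocytes and 0.25 for MHC class II. With mixed directions allowed, fry gave the chief and acinar lists 0.0033 and 0.0018 at 8 weeks. The list of sex-linked genes served as a check of the libraries. The lists cover parietal, chief, surface mucous, mucous neck and metaplasia, and enteroendocrine cells, squamous forestomach and intestinal epithelium, pancreatic acinar cells, hepatocytes, smooth and striated muscle, adipocytes, enteric neurons and glia, mesothelium, blood and lymphatic endothelium, erythroid, T and NK, B and plasma cells, macrophages and granulocytes, MHC class II, interferon response, cell cycle, extracellular matrix, fetal imprinted and early postnatal growth genes, galectins, lysosome and selective autophagy, integrins and galectin-8 ligands, oxidative phosphorylation, endoplasmic reticulum stress, immediate early and heat shock genes, and the circadian clock. A list's score is the mean log2 CPM of its members with a prior count of 2.

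The genes named follow a rule fixed before the data were examined. It takes Lgals8, up to 4 members of each list with the smallest p among those past the threshold (or 2 as values where a list passed and no member did), and the 8 genes with the largest change in each direction among called genes. These last genes must not overlap between the libraries compared and must have a mean log2 CPM of at least 1. Predicted gene models, pseudogenes and antigen receptor segments are left out of them. Where under 5 genes passed, the 10 with the smallest p are taken as values. A gene taken by this rule and a test of the strain background are not reported here, and counts include that gene.

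The procedure was tested on simulated counts with the dispersions of these libraries and 50 changed genes for each fold size among 19238. The changes were placed in KO_8wk only, in genes with a mean log2 CPM of at least 1. All groups otherwise had the same mean and the same spread per gene. The real KO_8wk pair differed more than the other pairs, so the rates may be too high for these data. The procedure found 20% of 1.5-fold, 54% of 2-fold, 92% of 4-fold and 90% of 8-fold changes, all with the right sign. Of its 148 calls, 20 were false, above the nominal rate, and it made 0 calls in a contrast where nothing changed.

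Alternatives fixed before the data were examined were other scalings (RLE, upper quartile, library totals without factors), no filter on low counts, a filter of at least 1 CPM in 2 libraries, DESeq2 1.42.0, limma voom, a fit to only the libraries compared, a block for the replicate number, leaving out each library in turn, an estimated correlation for lists, and lists without shared members. A squamous epithelium covariate, leaving out a pair of libraries, and an age slope over called genes were added after the data were seen. A fit without 1 library leaves its group with a lone sample, which is then assumed to vary like the other groups.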

Results

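The data are RNA-seq gene counts of 8 stomach libraries, 2 from each of 4 groups: wild-type and Lgals8-null mice at 3 and 8 weeks of age. Galectin-8 is a glycan-binding protein with a pair of carbohydrate recognition domains, and the series title asks about its role in stomach maturation. Library totals were 77758350 and 70988676 counts (WT, 3 weeks), 58851837 and 80686621 (WT, 8 weeks), 68917708 and 61800144 (KO, 3 weeks), and 69150262 and 65170447 (KO, 8 weeks). Pgc, the gene for pepsinogen C, was the most abundant transcript in all 8. It took 10.1% and 10.1% of counts in wild type and 8.1% and 8.6% in knockout at 3 weeks, and 23.3% and 23.6% in wild type and 13% and 15.5% in knockout at 8 weeks. Scaling by library totals in place of TMM moves the median of all genes by 0.35 for genotype at 8 weeks, by -0.56 and -0.27 for age in wild type and knockout, by 0.29 for the interaction and by 0.21 for genotype over both ages (log2). All changes below are relative to the TMM scaling. All libraries held transcripts of Y-linked genes, with Ddx3y between 24.1 and 32.7 CPM and Xist between 0.0673 and 1.25 CPM.

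Lgals8 (ENSMUSG00000057554, chromosome 13, 12439415 to 12464944, GRCm38) was measured at 34.2 ± 0.46 CPM in wild type and 2.24 ± 0.76 CPM in knockout at 3 weeks, and at 37.0 ± 0.82 and 3.05 ± 1.6 CPM at 8 weeks (SD, n = 2). The knockout level was 6.54% and 8.25% of wild type. Its genotype log2 fold change was -3.94 (SE 0.40) at 3 weeks, where the edgeR adjusted p of 0.13 did not pass, -3.60 (SE 0.39, adjusted p 0.040) at 8 weeks and -3.77 (SE 0.28, adjusted p 0.015) over both ages. Its level did not pass for age in wild type (log2 fold change 0.11, adjusted p 0.89) or knockout (0.44, adjusted p 0.50), nor for the interaction (0.33, adjusted p 0.88). Across the fits that leave out 1 library, the 8-week change stayed between -4.25 and -3.13, with an adjusted p under the threshold in 2 of 8.

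The comparison of genotypes at 3 weeks asks which transcripts differ between Lgals8-null and wild-type mice around weaning age. It includes any strain difference between the mice, in Mmrn1, Nnt and Wdfy1 as in other genes, and in neighbours of Lgals8 such as Ero1lb and Gpr137b. Mmrn1, the gene for the platelet and endothelial protein multimerin 1, had 0 counts in both knockout libraries against 7.55 ± 1.8 CPM in wild type (SD, n = 2), which makes it at least 194-fold lower (edgeR adjusted p 0.015). Rnf167, the gene for an endosomal and lysosomal E3 ubiquitin ligase, fell from 44.6 ± 2.8 to 17.8 ± 0.47 CPM (2.51-fold lower, adjusted p 0.0083). Nnt, the gene for the mitochondrial NAD(P) transhydrogenase, rose from 42.7 ± 0.34 to 96.0 ± 0.38 CPM (2.25-fold higher, adjusted p 0.030). These 3 of the 19647 genes tested passed (1 higher, 2 lower), with 1381 at an unadjusted p under 0.05 against 982 for chance. A fit to the 3-week libraries alone called 523 (258 higher, 265 lower), DESeq2 180 (86 and 94) and limma voom 6 (3 and 3). Gpr137b (log2 fold change 1.35), Wdfy1 (2.46), Ero1lb (-1.33), Aldh3a1 (0.76), Bcr (-3.29) and the pseudogene Marcksl1-ps4 (-3.19) came next with adjusted p from 0.056 to 0.14. Each of the 3 genes kept its direction in all 8 fits that leave out 1 library, and 2 of them passed without WT_8wk replicate 1 or WT_8wk replicate 2. The count of all called genes was 0 without WT_3wk replicate 1, WT_3wk replicate 2, KO_3wk replicate 1 or KO_3wk replicate 2, and 16 and 15 without KO_8wk replicate 1 and replicate 2.

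Among gene groups at 3 weeks, the erythroid list had 6 of 6 members below wild type (median log2 fold change -0.70, camera adjusted p 5.7e-08, adjusted p = 0.72 with an estimated correlation). No erythroid gene passed over all genes and 5 passed adjusted over the list alone. Hbb-bs was 70.7 ± 3.4 CPM in wild type and 41.8 ± 4.3 CPM in knockout, with the caveat that globin copies share reads. The cell cycle list had 17 of 18 members above wild type (median 0.20, camera adjusted p 0.00011, adjusted p = 0.72 with an estimated correlation), among them Rrm2 (0.31) and Birc5 (0.44), with 0 members past the threshold over all genes and 0 adjusted over the list alone. The macrophage and granulocyte list was higher (median 0.28, adjusted p 0.0046, adjusted p = 0.95 with an estimated correlation), as were immediate early and heat shock genes (median 0.35, adjusted p 0.028, adjusted p = 0.92 with an estimated correlation), with Jun at -0.35 and Egr1 at 0.37. Hepatocyte genes (median 4.49), smooth muscle genes (0.27) and striated muscle genes (1.05) were higher with camera adjusted p of 0.028, 0.028 and 0.029, each with adjusted p = 0.95 with an estimated correlation. Over all genes and adjusted over the list alone, 0 members of the macrophage, immediate early, hepatocyte and muscle lists passed. The hepatocyte score was 6.39 in KO_3wk replicate 2 against 1.29 to 2.11 in the other 3-week libraries, and without that library its adjusted p was 0.59. Calls were also lost without WT_3wk replicate 2 (smooth muscle 0.93, striated muscle 0.078), KO_3wk replicate 1 (smooth muscle 0.97, striated muscle 0.52), WT_3wk replicate 1 (immediate early 0.20) and KO_3wk replicate 2 (immediate early 0.19, macrophage 0.14).

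The comparison at 8 weeks asks the same in the young adult stomach. Pgc fell from 306000 ± 2100 to 146000 ± 20000 CPM (SD, n = 2, 2.10-fold lower, edgeR adjusted p 0.043). Chia1, the gene for acidic chitinase, fell from 36800 ± 610 to 11600 ± 2300 CPM (3.16-fold lower, adjusted p 0.042). Bhlha15, the gene for the secretory cell transcription factor MIST1, fell from 92.3 ± 20 to 40.1 ± 5.2 CPM (2.30-fold lower, adjusted p 0.047). Sst, the gene for somatostatin, fell from 582 ± 50 to 262 ± 16 CPM (2.22-fold lower, adjusted p 0.012), and Ghrl, the gene for ghrelin, from 1400 ± 63 to 732 ± 90 CPM (1.92-fold lower, adjusted p 0.035). The interaction with age did not pass for Pgc, Sst or Ghrl (adjusted p 0.53 each). Of 19647 genes tested, 16 rose and 48 fell, with 3776 at an unadjusted p under 0.05 against 982 for chance. More genes rose than fell under library totals (5355 and 102), with DESeq2 (1010 and 747), and without KO_8wk replicate 1 (970 and 285), KO_8wk replicate 2 (688 and 471) or WT_8wk replicate 1 (2 and 1).

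Of 9 chief cell genes tested at 8 weeks, 3 fell and 6 did not pass, and 6 were lower when adjusted over the list alone (median log2 fold change -0.44, camera adjusted p 5.4e-05, adjusted p = 0.51 with an estimated correlation). Of 15 enteroendocrine genes, 2 fell and 5 were lower adjusted over the list alone. The list's median was -0.21 and its mean 0.33, while camera placed it lower (adjusted p 0.0032, adjusted p = 0.51 with an estimated correlation). None of 14 parietal cell genes, which serve acid secretion, passed over all genes and 3 were lower adjusted over the list alone (median -0.27, adjusted p 0.00014, adjusted p = 0.52 with an estimated correlation), with Kcnj15 at -0.48 and Kcnq1 at -0.44. Scaling by library totals moved the chief median to -0.09, the parietal median to 0.08 and the enteroendocrine median to 0.14, and left Pgc (-0.72), Chia1 (-1.31), Bhlha15 (-0.85), Sst (-0.80) and Ghrl (-0.59) lower. Of 11 pancreatic acinar genes, Try4 fell 4.25-fold (adjusted p 0.037), a trypsinogen whose near-identical copies make its counts uncertain, and 4 were lower adjusted over the list alone (median -1.18, adjusted p 0.00035, adjusted p = 0.43 with an estimated correlation). Mucous neck and metaplasia genes were higher as a list (median 0.49, adjusted p 0.0035, adjusted p = 0.51 with an estimated correlation), with 0 of 11 past the threshold over all genes and 3 higher and 1 lower adjusted over the list alone. Clu was at 0.49 and Tff2, the gene for a trefoil peptide, at 0.41. Leaving out KO_8wk replicate 1 ended the calls of the parietal (0.055), mucous neck (0.19) and enteroendocrine (0.063) lists.

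Transcripts of immune cells were higher as lists in the 8-week knockout, without a member past the threshold over all genes. B and plasma cell genes had a median log2 fold change of 3.65, or 2.89 with the gene at 0 in wild type at its bound (camera adjusted p 2.2e-05, adjusted p = 0.51 with an estimated correlation), and 7 of 10 were higher adjusted over the list alone. Igha, the IgA heavy chain, was 8.27 ± 5.4 CPM in wild type and 353 ± 270 CPM in knockout, and Jchain was 0.972 ± 0.40 and 49.2 ± 35 CPM. MHC class II genes (median 1.57, adjusted p 0.00014, adjusted p = 0.52 with an estimated correlation) had 7 of 7 higher adjusted over the list alone. Macrophage and granulocyte genes (median 0.63, adjusted p 2.2e-05, adjusted p = 0.51 with an estimated correlation) had 9 of 11, with C1qc at 0.82 and C1qa at 0.89. Interferon response genes (median 1.62, adjusted p 0.00077, adjusted p = 0.54 with an estimated correlation) had 0 of 14, with Bst2 at 1.58 and Ifi44 at 2.41. T and NK cell genes (median 2.14, adjusted p 0.0037, adjusted p = 0.54 with an estimated correlation) had 1 of 11, with Trac at 4.75 and Cd8a at 3.21. KO_8wk replicate 1 stood apart, with scores of 1.15 for T and NK cells, 5.50 for interferon response and 6.59 for MHC class II, against -1.37, 3.40 and 5.05 in KO_8wk replicate 2 and at most -1.58, 3.58 and 4.44 in wild type at 8 weeks. Without it the T and NK call (0.54) and the interferon call (0.55) ended, and the T and NK call also ended without WT_8wk replicate 2 (0.064). B and plasma cell scores were 2.82 and 1.13 in the knockout and -0.71 and -1.56 in wild type.

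Other lists past camera at 8 weeks were mesothelium (median log2 fold change 4.25, or 3.65 with Wt1 at its bound, adjusted p 0.0032, adjusted p = 0.53 with an estimated correlation), with Msln at 3.21 ± 2.7 CPM in knockout and 0.0751 ± 0.075 CPM in wild type. Blood and lymphatic endothelium was lower (median -0.21, 0.14 under library totals, adjusted p 0.041, adjusted p = 0.54 with an estimated correlation), with Emcn at -0.57 and Kdr at -0.47. Cell cycle genes were higher (median 0.22, adjusted p 0.0043, adjusted p = 0.51 with an estimated correlation), with Top2a at 0.27. So were immediate early and heat shock genes (median 0.34, adjusted p 0.017, adjusted p = 0.51 with an estimated correlation), with Egr1 at 0.79. Oxidative phosphorylation genes (median -0.12, adjusted p 0.0064, adjusted p = 0.54 with an estimated correlation) and lysosome and selective autophagy genes (median -0.09, adjusted p 0.0087, adjusted p = 0.53 with an estimated correlation) were lower, with medians of 0.23 and 0.26 under library totals. In these lists 0 members passed over all genes, and adjusted over the list alone 4 mesothelial genes were higher, 3 endothelial genes lower and 1 immediate early gene higher. Without WT_8wk replicate 1 the endothelial (0.34), cell cycle (0.060), lysosome (0.27), oxidative phosphorylation (0.10) and immediate early (0.32) calls ended. Without KO_8wk replicate 1 the endothelial (0.37), cell cycle (0.055), oxidative phosphorylation (0.12) and immediate early (0.47) calls ended, and without KO_8wk replicate 2 the cell cycle call (0.076).

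The named genes with the largest 8-week changes included Wdfy1 (5.16-fold higher, edgeR adjusted p 0.035), Adamts4 (3.77-fold), Tnfrsf12a, the gene for the TWEAK receptor (2.76-fold), Kif21b, Crlf2, Gpr137b and Fmnl1 (2.10-fold), all higher with adjusted p up to 0.044. Lower were Mmrn1 (at least 152-fold), the helicase gene Blm (3.63-fold), Ripor3 (3.57-fold), Gdf9 (3.47-fold), Dio1, the gene for type I deiodinase (3.12-fold), and Ush1g (3.00-fold), with adjusted p from 0.012 to 0.044. Any strain difference between the mice is part of these changes too, in Mmrn1, Wdfy1 and the Lgals8 neighbour Gpr137b as in other genes. All 21 called genes that the naming rule took at 8 weeks kept their direction in all 8 fits that leave out 1 library. Of them, 21 passed without KO_8wk replicate 1 and 21 without KO_8wk replicate 2. The number passing was 0 without WT_3wk replicate 1 or WT_3wk replicate 2, 1 without WT_8wk replicate 1, KO_3wk replicate 1 or KO_3wk replicate 2, and 5 without WT_8wk replicate 2. The count of 64 genes became 1, 1, 3, 18, 2 and 2 without WT_3wk replicate 1, WT_3wk replicate 2, WT_8wk replicate 1, WT_8wk replicate 2, KO_3wk replicate 1 and KO_3wk replicate 2. It became 1255 and 1159 without KO_8wk replicate 1 and replicate 2. A fit to the 8-week libraries alone called 0 genes, with 2046 at an unadjusted p under 0.05, while DESeq2 called 1757 and limma voom 28. Counts of the KO_8wk pair differed more than those of other pairs (chi-square per degree of freedom 101.4 against 31.6, 34.9 and 34.2). Their Pearson r of log2 CPM was 0.9656, against 0.9631 in WT_8wk. All groups share 1 spread estimate per gene, which may be too small for KO_8wk. A fit without a KO_8wk library drops that pair's spread, so calls kept or gained there add no support.

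**Figure D1:**
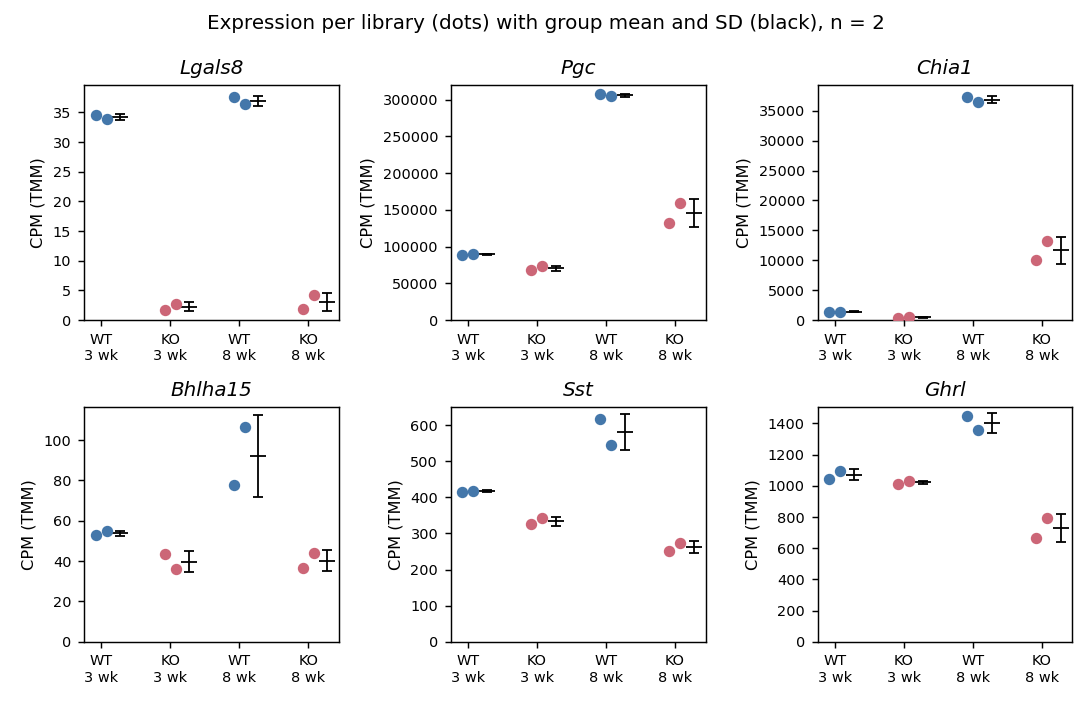
CPM after TMM scaling of Lgals8, Pgc, Chia1, Bhlha15, Sst and Ghrl in each of the 8 libraries (dots), with the group mean and SD in black (n = 2). In the 8-week knockout both libraries lie below both wild-type libraries for all 6 genes.

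The age comparison in wild type describes maturation from 3 to 8 weeks. Chia1 was 26.3-fold higher at 8 weeks (edgeR adjusted p 0.00024), Pgc 3.43-fold (0.00094), Muc5ac, the main surface mucin, 4.17-fold (0.00083), and Psca 2.92-fold (0.00033). Cym, the gene for the milk-clotting protease chymosin, went from 30500 ± 7800 to 32.2 ± 29 CPM (SD, n = 2; adjusted p 0.027), H19, an imprinted growth-related RNA, was 14.0-fold lower (6.0e-04), and Col1a1 went from 1740 ± 180 to 485 ± 11 CPM (0.00024). Of 19647 genes, 1359 rose and 1455 fell, with 5487 at an unadjusted p under 0.05. Upper-quartile scaling changed the split to 1663 and 1339, and library totals changed it to 185 and 9413.

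By list, extracellular matrix genes fell in 15 of 17 members (median -1.49, camera adjusted p 1.4e-16, adjusted p = 0.23 with an estimated correlation), with 16 lower and 1 higher adjusted over the list alone, and Col5a2, Col1a2 and Col5a1 2.97-, 2.81- and 3.19-fold lower. Cell cycle genes fell in 9 of 18, 13 adjusted over the list alone (median -0.57, adjusted p 3.3e-07, adjusted p = 0.23 with an estimated correlation), as Top2a, Mcm6, Mcm3 and Mcm5 show at 1.93-, 1.66-, 1.69- and 1.69-fold lower. Fetal imprinted and early postnatal growth genes fell in 7 of 12, 8 adjusted over the list alone (median -0.96, adjusted p 2.4e-05, adjusted p = 0.23 with an estimated correlation), including Igf2bp3 (19.7-fold) and Mest (3.52-fold). Integrin and galectin-8 ligand genes fell in 7 of 14, 11 adjusted over the list alone (median -0.62, adjusted p 2.5e-06, adjusted p = 0.30 with an estimated correlation), among them Itga6 (2.13-fold) and Itga2 (4.95-fold). Endothelial genes fell in 4 of 11, 5 adjusted over the list alone (median -0.35, adjusted p 0.0057, adjusted p = 0.47 with an estimated correlation), among them Cdh5. Erythroid genes fell in 2 of 6, 3 adjusted over the list alone (median -0.56, adjusted p 0.0086, adjusted p = 0.53 with an estimated correlation), among them Slc4a1.

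Surface mucous cell genes rose in 7 of 12 members, 7 adjusted over the list alone (median 0.58, camera adjusted p 7.1e-07, adjusted p = 0.32 with an estimated correlation). Chief cell genes rose in 6 of 9, 6 adjusted over the list alone (median 0.87, adjusted p 0.00071, adjusted p = 0.30 with an estimated correlation). Pga5, another pepsinogen gene, moved the other way, 6.74-fold lower. Parietal cell genes rose in 8 of 14, 12 adjusted over the list alone (median 0.55, -0.01 under library totals, adjusted p 3.2e-06, adjusted p = 0.32 with an estimated correlation), including Atp4b, a subunit of the proton pump (1.68-fold), and Kcnj16 (1.80-fold). Pancreatic acinar genes rose in 5 of 11, 5 adjusted over the list alone (median 0.81, adjusted p 0.00039, adjusted p = 0.23 with an estimated correlation), led by trypsinogens whose copies share reads. Oxidative phosphorylation genes rose in 11 of 22, 16 adjusted over the list alone (median 0.33, -0.24 under library totals, adjusted p 2.9e-09, adjusted p = 0.30 with an estimated correlation), among them Cox7a2. Lysosome and selective autophagy genes rose in 10 of 17, 11 adjusted over the list alone (median 0.34, -0.22 under library totals, adjusted p 1.6e-06, adjusted p = 0.30 with an estimated correlation), among them Gabarapl1 (2.43-fold) and Ctsd (1.51-fold). Endoplasmic reticulum stress genes rose in 2 of 12, 5 adjusted over the list alone (median 0.68, adjusted p 0.00031, adjusted p = 0.48 with an estimated correlation), among them Xbp1. Clock genes rose in 4 of 13, 5 adjusted over the list alone (median 0.27, -0.28 under library totals, adjusted p 0.016, adjusted p = 0.30 with an estimated correlation), among them Dbp. The time of day of sampling is not given in the sources used here. Without WT_8wk replicate 2 the endothelial (0.11), erythroid (0.23), endoplasmic reticulum stress (0.098) and clock (0.17) calls ended.

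In lists without a camera call in wild type, genes went both ways, with edgeR adjusted p up to 0.046. Higher were Chga (1.83-fold), Slc18a2 (1.52-fold), Tff2 (1.56-fold), Apoa1 (2.66-fold), Rbp2 (1.84-fold), Apoa4 (1.64-fold), Tnnt3 (14.2-fold), Igha (96.6-fold), Lgals2 (2.37-fold), S100a8 (1.89-fold), Lyz2 (2.17-fold) and Junb (1.55-fold). Lower were Pyy (3.38-fold), Sox9 (1.45-fold), Cftr (4.35-fold), Alpi (12.1-fold), Lgals3 (1.61-fold), Lgals4 (1.53-fold), Csf1r (1.54-fold), Egr1 (1.81-fold) and Dusp1 (1.52-fold). Further genes with large changes were the trypsinogen Try10 (66.3-fold higher, reads uncertain), Dmbx1 (32.7-fold), Piwil4 (12.0-fold) and Gdf9 (9.54-fold). Lower were the mucin Muc5b (91.4-fold), Bpifb1 (38-fold), Fbn2, a microfibril gene of developing tissue (12.1-fold), and Scnn1b (8.98-fold). All 85 called genes named for wild type kept their direction when 1 library was left out, and 35 passed in all 8 such fits. The total count of 2814 became 382, 397, 1448, 1685, 1745 and 1773 without WT_3wk replicate 1, WT_3wk replicate 2, WT_8wk replicate 1, WT_8wk replicate 2, KO_3wk replicate 1 and KO_3wk replicate 2.

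The same age comparison in the knockout asks whether these changes take place without Lgals8. Chia1 rose 25.7-fold (edgeR adjusted p 0.00025), Pgc 2.06-fold (0.0072), Psca 2.43-fold (7.0e-04), Gkn1 2.45-fold (0.0028) and Egf, the gene for epidermal growth factor, from 4.13 ± 0.48 to 44.4 ± 1.1 CPM (SD, n = 2; 2.0e-04). Cym fell from 30100 ± 3500 to 104 ± 120 CPM (0.045), H19 was 17.4-fold lower (0.00053), Col1a1 3.58-fold (0.00025) and Eln, the elastin gene, 8.34-fold (4.0e-04). Sst (1.27-fold lower, 0.046) and Ghrl (1.40-fold lower, 0.026) fell with age here, while Sst rose 1.39-fold in wild type (0.013; log2 fold change -0.08, adjusted p 0.42, under library totals), with an interaction adjusted p of 0.53 for both genes. In all, 828 genes rose and 1287 fell, with 5532 at an unadjusted p under 0.05. Upper-quartile scaling changed the split to 1019 and 1160, library totals to 386 and 4852. More genes rose than fell with DESeq2 (1972 and 1794) and without KO_8wk replicate 1 (1475 and 1333), and a fit to the knockout libraries alone called 241 (66 higher, 175 lower).

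In the knockout, extracellular matrix genes fell in 15 of 17 members (16 adjusted over the list alone, median -1.53, camera adjusted p 2.9e-19, adjusted p = 0.24 with an estimated correlation). Cell cycle genes fell in 9 of 18 (12, median -0.62, 1.1e-08, adjusted p = 0.24 with an estimated correlation). Fetal and early growth genes fell in 6 of 12 (7, median -0.98, 3.8e-06, adjusted p = 0.24 with an estimated correlation). Integrin and ligand genes fell in 7 of 14 (8 lower and 1 higher, median -0.42, 2.1e-05, adjusted p = 0.40 with an estimated correlation). Endothelial genes fell in 2 of 11 (4, median -0.33, 0.00073, adjusted p = 0.40 with an estimated correlation). Surface mucous genes rose in 6 of 12 (6, median 0.72, 3.8e-06, adjusted p = 0.40 with an estimated correlation). Endoplasmic reticulum stress genes rose in 3 of 12 (5, median 0.62, 3.3e-05, adjusted p = 0.44 with an estimated correlation). Lysosome genes rose in 7 and fell in 1 of 17 (10 and 2, median 0.27, 0.00073, adjusted p = 0.40 with an estimated correlation). Oxidative phosphorylation genes rose in 3 of 22 (6, median 0.18, -0.09 under library totals, 0.00091, adjusted p = 0.59 with an estimated correlation). Parietal genes rose in 2 of 14 (6 higher and 1 lower, median 0.17, -0.10 under library totals, 0.030, adjusted p = 0.61 with an estimated correlation). Pancreatic acinar genes rose in 2 of 11 (2, median 0.63, 0.046, adjusted p = 0.40 with an estimated correlation). Clock genes rose in 4 and fell in 1 of 13 (4 and 1, median 0.30, 0.025, adjusted p = 0.40 with an estimated correlation). In these sentences each parenthesis opens with the count adjusted over the list alone, and the p without further words is camera's adjusted p.

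B and plasma cell genes rose in 2 of 10, Igha (232-fold, edgeR adjusted p 0.017) and Jchain. Igha also rose with age in wild type (96.6-fold, edgeR adjusted p 0.036). Across the fits that leave out 1 library, the log2 fold change of Igha ran from 6.73 to 8.48 in knockout and 5.72 to 8.25 in wild type. Of the list, 5 were higher adjusted over the list alone (median 2.11, camera adjusted p 0.0028, adjusted p = 0.59 with an estimated correlation). MHC class II genes had 0 of 7 past the threshold over all genes and 7 adjusted over the list alone (median 1.70, 0.00094, adjusted p = 0.59 with an estimated correlation). T and NK cell genes had 0 of 11 and 3 (median 2.17, 0.023, adjusted p = 0.61 with an estimated correlation). Interferon response genes had 0 of 14 and 0 (median 1.81, 0.00073, adjusted p = 0.61 with an estimated correlation). Myh11 fell 2.01-fold (edgeR adjusted p 0.019) in the smooth muscle list, where 3 of 11 were lower adjusted over the list alone (median -0.38, camera adjusted p 0.038, adjusted p = 0.63 with an estimated correlation). Mesothelial genes passed narrowly (median 1.53, camera adjusted p 0.050, adjusted p = 0.61 with an estimated correlation). Lrrn4, 29.8-fold higher (edgeR adjusted p 0.026), was the 1 member past the threshold, over all genes and over the list alone. Its log2 fold change ran from 2.91 to 5.71 across the fits that leave out 1 library. That mesothelium list call ended without WT_8wk replicate 1 (0.068), WT_8wk replicate 2 (0.068), KO_3wk replicate 1 (0.071) or KO_8wk replicate 2 (0.54), and under RLE (0.059) and upper-quartile scaling (0.068). Chief cell genes had no camera call (median 0.34, adjusted p 0.13), with 3 higher and 1 lower. Without KO_8wk replicate 1 the T and NK (0.62), interferon (0.087), smooth muscle (0.30) and acinar (0.10) calls ended. Without KO_8wk replicate 2 the parietal (0.45), oxidative phosphorylation (0.11), clock (0.14) and acinar (0.14) calls ended. Without KO_3wk replicate 1 the smooth muscle call ended (0.39), and without KO_3wk replicate 2 the acinar call (0.11). All 70 called genes named kept their direction in these fits and 23 passed in all 8. The count of 2115 became 1007, 1001, 268 and 302 without WT_3wk replicate 1, WT_3wk replicate 2, KO_3wk replicate 1 and KO_3wk replicate 2.

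**Figure D2:**
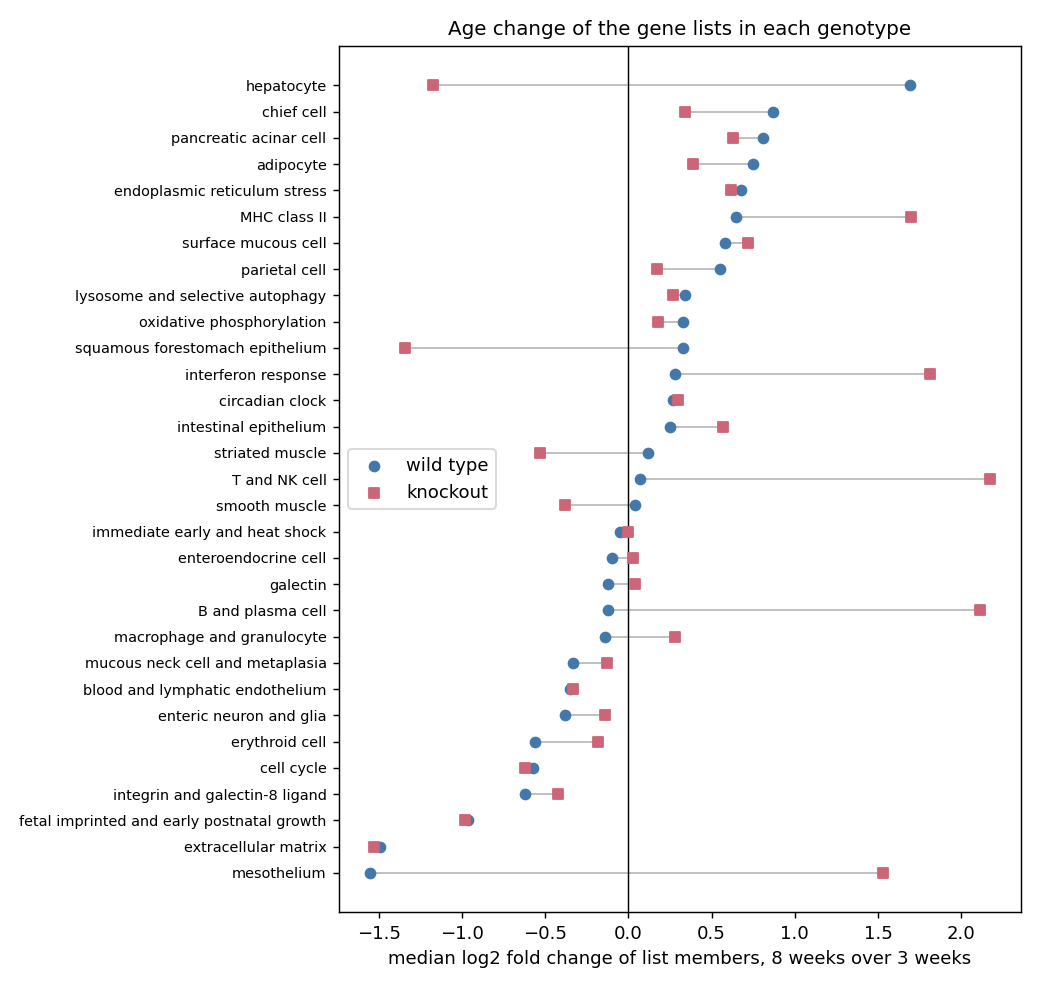
Median log2 fold change with age (8 weeks over 3 weeks) of the tested members of each of 31 gene lists, in wild type (circles) and knockout (squares). Extracellular matrix genes lie at -1.49 and -1.53, while chief cell genes lie at 0.87 and 0.34 and B and plasma cell genes at -0.12 and 2.11; without factors for scaling, every wild-type value shifts by about -0.56 and every knockout value by about -0.27.

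Of the genes called with age, 2814 in wild type and 2115 in knockout, 1371 were called in both. Of these, 540 were higher and 828 lower at 8 weeks in both, and 3 went in opposite directions. Independent draws of genes would share 57.3 higher and 95.3 lower. Both contrasts use the same spread estimate per gene, so lists of unrelated effects could overlap more than that. Of the 3558 genes called in either genotype, 94.5% had the same sign in both. Across all 19647 genes the 2 age effects had a Pearson r of 0.301 and a Spearman rho of 0.386, and genes are not independent replicates. The orthogonal slope of knockout on wild type was 1.509, and 0.929 over genes called for the mean age effect, a set chosen after the data were seen. It varied with single libraries: it was 0.401 without WT_3wk replicate 1, 1.082 without WT_3wk replicate 2, 0.999 without WT_8wk replicate 1, 0.159 without WT_8wk replicate 2, 3.945 without KO_3wk replicate 1, 2.981 without KO_3wk replicate 2, 3.355 without KO_8wk replicate 1 and 2.960 without KO_8wk replicate 2.

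The interaction asks whether the change with age differs between genotypes. The genes with the smallest p were Aldh3a1 (148 to 414 CPM with age in wild type, 251 to 343 CPM in knockout), Anpep (324 to 322 and 308 to 181 CPM), Sst (417 to 582 and 334 to 262 CPM), Adh7 (82.1 to 150 and 108 to 99.4 CPM) and Arid3a (14.5 to 7.62 and 11.1 to 11.6 CPM), followed by Gstm7, Umod, Gstm2, Mustn1 and Macrod1. None passed: edgeR called 0 genes, the smallest adjusted p was 0.526, and 1727 genes had an unadjusted p under 0.05 against 982 for chance. DESeq2 called 175 and limma voom 0; edgeR called 419 without KO_8wk replicate 1 and 121 without KO_8wk replicate 2. So the genes called for genotype at 8 weeks and not at 3 weeks are not shown to differ between ages; Pgc (log2 difference -0.73), Sst (-0.83), Ghrl (-0.87) and Try4 (-1.43) each had an adjusted p of 0.53. Between the genotype effects at 3 and 8 weeks, Pearson r across genes was 0.299 and Spearman rho 0.244, and 61 of the 64 genes called at 8 weeks had the same sign at 3 weeks. Camera called 16 lists for the interaction, 0 of them with an estimated correlation (smallest adjusted p = 0.64), and their values are given in the closing section.

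The mean genotype effect over both ages compares 4 knockout with 4 wild-type libraries. Mmrn1 had 0 counts in all 4 knockout libraries (adjusted p 0.0023), Rnf167 was 2.72-fold lower (SE 0.060 on the log2 scale, edgeR adjusted p 0.00033), and Wdfy1, an endosomal adaptor gene, was 5.32-fold higher (0.0074). Bcr was 7.34-fold lower (0.021), Ero1lb, an endoplasmic reticulum oxidase gene, 2.50-fold lower (0.0074), and Nnt 1.85-fold higher (0.0086). Of the 19647 genes, 17 rose and 66 fell, with 3607 at an unadjusted p under 0.05. More genes rose than fell under library totals (2955 and 108), with DESeq2 (779 and 637), and without KO_8wk replicate 1 (710 and 379) or replicate 2 (617 and 460). The comparison includes any strain difference between the mice, in Mmrn1, Wdfy1 and Nnt as in other genes. Chia1 (3.12-fold), Pgc (1.63-fold), Bhlha15 (1.76-fold), Sst (1.67-fold), Ghrl (1.42-fold) and the acinar genes Try4 (2.59-fold) and Sycn (2.06-fold) were among the lower, with adjusted p from 0.0088 to 0.045. Also called were Gpr137b, Tnfrsf12a, Epdr1, Icam1 and the cell cycle inhibitor gene Cdkn2b (1.45- to 2.37-fold higher) and Blm, Ripor3, Btnl9 and Entpd4b (2.28- to 2.47-fold lower; Entpd4b has a near-identical copy). Of the 24 called genes that the rule took, all kept their direction and Mmrn1 and Rnf167 passed in all 8 fits that leave out 1 library. The count of 83 became 2 without WT_3wk replicate 1, WT_3wk replicate 2 or KO_3wk replicate 1, 10 without WT_8wk replicate 1, 7 without KO_3wk replicate 2, 1089 without KO_8wk replicate 1 and 1077 without KO_8wk replicate 2.

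Over both ages, chief cell genes were lower in the knockout as a list (median -0.18, 0.02 under library totals, camera adjusted p 0.00054, adjusted p = 0.50 with an estimated correlation). The other lower lists follow with their median, camera adjusted p and the p with an estimated correlation. Enteroendocrine genes had a median of -0.14 and a mean of 0.12, with a median of 0.06 under library totals (0.0027, adjusted p = 0.50 with an estimated correlation). Pancreatic acinar genes had -0.87 (0.0023, adjusted p = 0.48 with an estimated correlation) and parietal genes -0.15, or 0.06 under library totals (0.0026, adjusted p = 0.61 with an estimated correlation). Surface mucous genes had -0.13, or 0.08 under library totals (0.019, adjusted p = 0.77 with an estimated correlation). Endothelial genes had -0.14, or 0.07 under library totals (0.019, adjusted p = 0.61 with an estimated correlation), and erythroid genes -0.51 (0.00051, adjusted p = 0.50 with an estimated correlation). Higher were macrophage and granulocyte genes (0.52, 8.4e-06, adjusted p = 0.50 with an estimated correlation) and cell cycle genes (0.21, 0.00015, adjusted p = 0.48 with an estimated correlation). MHC class II genes (1.09, 0.00051) and B and plasma cell genes (1.67, 0.0014) were higher, both with adjusted p = 0.61 with an estimated correlation. So were immediate early genes (0.32, 0.0045) and mucous neck genes (0.40, 0.0075), both with adjusted p = 0.50 with an estimated correlation. Mesothelial genes (2.64, or 1.96 with Wt1 at its floor, 0.013, adjusted p = 0.61 with an estimated correlation) and T and NK cell genes (0.95, 0.026, adjusted p = 0.77 with an estimated correlation) were also higher. Adjusted over the list alone, 4 chief, 5 enteroendocrine, 2 acinar, 2 parietal, 0 surface mucous, 3 endothelial and 4 erythroid genes were lower. By the same count 8 macrophage, 0 cell cycle, 6 MHC class II, 6 B and plasma, 5 immediate early, 3 mucous neck, 4 mesothelial and 1 T and NK genes were higher, with 1 immediate early and 1 mucous neck gene lower. Calls ended without KO_8wk replicate 1 (parietal 0.059, mucous neck 0.13, endothelial 0.12, T and NK 0.54, immediate early 0.071), WT_8wk replicate 1 (surface mucous 0.27, endothelial 0.11, immediate early 0.056), WT_8wk replicate 2 (mesothelial 0.064, T and NK 0.12) and KO_8wk replicate 2 (surface mucous 0.14).

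Called genes lay near Lgals8 more often than tested genes did. Within 20 Mb of Lgals8 on chromosome 13 lay 8 of 82 called genes with a position, Lgals8 apart (9.8%), against 171 of 19646 tested genes (0.87%), a ratio of 11.2 (Fisher's exact test, two-sided, p = 5.8e-07). They were Ero1lb (log2 fold change -1.32, start 0.13 Mb after that of Lgals8), Gpr137b-ps (-2.20, 0.18 Mb), Gpr137b (1.25, 0.92 Mb), Epdr1 (0.97, 7.15 Mb), Hist1h2ap (1.73, 9.39 Mb), Akr1c14 (-0.75, -8.39 Mb), Akr1c19 (-0.96, -8.21 Mb) and Marcksl1-ps4 (-3.49, -8.19 Mb). Hist1h2ap, the Akr1c genes and the pseudogenes have close copies, which makes their counts uncertain. Genes counted as neighbours are not independent of each other, and genes outside the naming rule were named here after their values were seen.

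**Figure D3:**
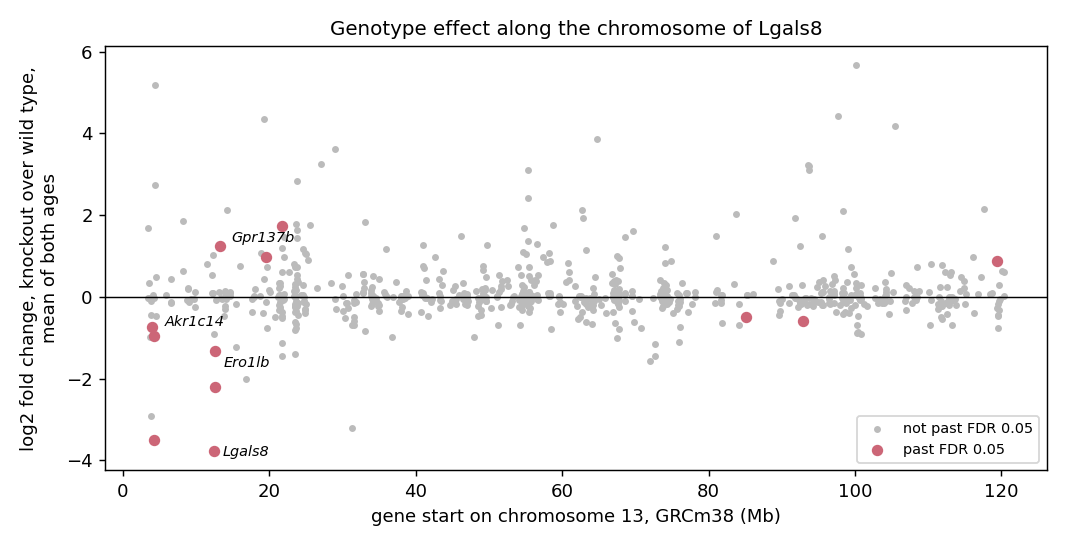
Genotype log2 fold change over both ages of tested genes along chromosome 13 (GRCm38, gene start in Mb), with genes past an adjusted p of 0.05 in red. Of 12 such genes, Lgals8 included, 9 lie within 20 Mb of Lgals8.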

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

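For 16 of the 31 gene lists, camera called the change with age different between genotypes, which is what marks them here. All 16 calls are lost with an estimated correlation (adjusted p 0.64 to 0.72), and no gene passed edgeR for the same contrast. The explanations of a few genes taking most of the counts, of the acid-secreting corpus and of lymphoid tissue were written after the result was seen, and the squamous forestomach and delayed maturation explanations before. The squamous covariate itself was added after the data were seen, so its test was not among the alternatives fixed beforehand. The rules for abundant genes, the acid-secreting corpus and lymphoid tissue were also changed after their values were seen.

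Lists that gained less or lost more with age in the knockout were chief (median log2 difference -0.53, camera adjusted p 0.0029) and parietal genes (-0.25, 0.0029, median 0.04 under library totals). Camera placed enteroendocrine genes lower too (median -0.21, 0.08 under library totals, adjusted p 0.016), but their mean was 0.42 and their age medians were -0.10 in wild type and 0.03 in knockout, so no direction is given for them. The direction of the chief list held for pancreatic acinar (-0.58, 0.047), smooth muscle (-0.46, 0.0031), oxidative phosphorylation (-0.18, 0.00047, median 0.11 under library totals) and lysosome and selective autophagy genes (-0.13, 0.0093, median 0.16 under library totals). Lists that gained more or lost less were interferon response (1.71, 0.0027), erythroid (0.32, 0.0074), B and plasma cell (2.20, or 2.13 with the gene at 0 at its floor, 0.0093) and macrophage and granulocyte genes (0.43, 0.0093). The same direction held for mesothelium (2.91, also with Wt1 at its floor, 0.0093), MHC class II (1.07, 0.015), T and NK cell (2.11, 0.017), galectin (0.17, 0.041) and mucous neck and metaplasia genes (0.40, 0.048). Each of these had adjusted p = 0.64 to 0.72 with an estimated correlation. Without KO_8wk replicate 1 the calls ended for the parietal (0.21), mucous neck (0.60), enteroendocrine (0.21), acinar (0.17), smooth muscle (0.18) and erythroid (0.12) lists. The same holds for the T and NK (0.78), B and plasma (0.27), macrophage (0.33), MHC class II (0.54), interferon (0.27) and galectin (0.21) lists. Without WT_8wk replicate 2 they ended for mucous neck (0.11), enteroendocrine (0.099), acinar (0.12), smooth muscle (0.11), mesothelium (0.099), erythroid (0.25), T and NK (0.13), B and plasma (0.12), macrophage (0.12), MHC class II (0.099) and galectin (0.12). Without WT_3wk replicate 1 they ended for mucous neck (0.25) and galectin (0.12), and without WT_3wk replicate 2 for acinar (0.12) and smooth muscle (0.084). Without WT_8wk replicate 1 they ended for mucous neck (0.063), galectin (0.051) and lysosome (0.10). Without KO_3wk replicate 1 they ended for acinar (0.097), smooth muscle (0.11) and MHC class II (0.051), and without KO_3wk replicate 2 for mucous neck (0.12), galectin (0.15) and lysosome (0.051). Without KO_8wk replicate 2 they ended for acinar (0.062) and mesothelium (0.15). The chief and oxidative phosphorylation lists passed in all 8 fits that leave out 1 library. The rule for a sample far from its group was not applied, since each group has 2 libraries.

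The lower chief and enteroendocrine transcripts called at 8 weeks were weighed against technical causes. The enteroendocrine list was not lower by every measure. Its mean log2 fold change was 0.33, and its scores were 3.08 and 3.03 in knockout and 2.97 and 3 in wild type. The 10 most abundant genes took 44.2% and 45.1% of counts in wild type and 28.6% and 32.2% in knockout. The median log2 fold change of all 24 tested chief and enteroendocrine genes was -0.34 with TMM (SE 0.52, from the spread over genes, not libraries). It was -0.35 with RLE, -0.32 with upper quartile and 0.01 under library totals, the highest of 4 scalings. Library totals do not correct for abundant genes and moved the median of all genes by 0.35. No value lay beyond the SE, which takes genes as independent, so a few genes taking most of the counts is left open for the lists as a whole. The 5 called genes Pgc, Chia1, Bhlha15, Sst and Ghrl stayed lower under library totals, as given above. They were chosen because they were called. With the squamous score as a covariate the median of the 5 called genes was -1.14, which met the rule against a different share of forestomach. Only Sst still passed (edgeR adjusted p 0.040, Pgc 0.098). These genes were chosen because they were called. The squamous scores did not separate the genotypes at 8 weeks (1.71 and 2.83 in knockout, -1.84 and 4.98 in wild type). The covariate could therefore hardly move the genes, and that test alone does not decide the question. The wild-type squamous scores lay on both sides of the knockout scores. The chief list scores were nonetheless 8.49 and 8.48 in wild type, against 7.74 and 8 in knockout, with TMM scaling. All 5 called genes were lower in both knockout libraries than in both wild-type libraries. For the chief list and these genes, the values argue against a different share of forestomach, on 2 libraries per group. Delayed maturation as a general cause met the rule written against it. Of age genes, 46.3% had a knockout effect opposed to their age effect, where simulations gave 49.2% to 52.6%. The share was 50.1% without KO_8wk replicate 1 and 44.1% without replicate 2. The KO_8wk libraries enter both effects with the same sign, which lowers the share. The WT_8wk libraries enter them with opposite signs, which raises it. Counts of the KO_8wk pair differed more than those of other pairs (chi-square per degree of freedom 101.4 against 31.6 to 34.9). The simulations gave all groups the same spread per gene, so this test cannot exclude a delay. A smaller share of acid-secreting corpus in the knockout samples could not be told apart. Parietal minus chief was 0.17 with an SE of 0.28, again from the spread over genes. This met the rule as first written. The rule was then changed to leave the question open, because the test is too coarse to separate the outcomes.

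Higher immune transcripts at 8 weeks could come from a piece of lymphoid tissue in the knockout samples. The T and NK score lay 2.73 above the higher wild-type library in KO_8wk replicate 1 and 0.21 in replicate 2, while the B and plasma cell score lay 3.53 and 1.84 above. The rule as first written would have counted replicate 2 against this cause; it was changed after the values were seen to ask for both libraries, which leaves the question open, since 1 library of a pair excludes nothing. An effect of the genotype on mucosal immune cells may remain, and 2 libraries cannot separate it from sampling.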

How the results depend on the processing

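Calls depend strongly on the processing. Scaling by RLE or upper quartile, a filter of at least 1 CPM and a block for the replicate number kept every count of genes within 1.5 times. Other settings did not, and the cause was not tested. In the order genotype at 3 weeks, at 8 weeks, age in wild type, age in knockout, interaction and both ages, the counts were 4, 5457, 9598, 5238, 0 and 3063 with library totals, 23, 441, 2968, 2399, 0 and 383 with no filter on low counts. They were 180, 1757, 3901, 3766, 175 and 1416 with DESeq2, and 6, 28, 2744, 2129, 0 and 56 with limma voom. A fit to only the libraries compared gave 523, 0, 3139 and 241 for the first 4. Chosen after seeing the data, the squamous covariate gave 2, 3, 2344, 1644, 0 and 29, and leaving out KO_3wk replicate 2 with KO_8wk replicate 1 gave 8, 765, 3198, 814, 0 and 296. Leaving out 1 library gave 0 to 16, 1 to 1255, 382 to 4123, 268 to 3008, 0 to 419 and 2 to 1089, and an age slope of 0.159 to 3.945. The total of 86 list calls became 0 with an estimated correlation and 65 to 96 without 1 library, where calls were gained as well as lost. Replicate numbers follow the sample titles and showed no common pairing (correlations of deviations from -0.46 to 0.47, the highest between the 3-week groups). By library name, WT_8wk replicate 2 carries the number of the 3-week replicate 1 libraries, and no KO_8wk library does. WT_8wk deviations ran against both 3-week groups (-0.46 and -0.42). The squamous scores of the libraries so numbered were the highest (4.63, 4.63 and 4.98). A pairing by name is thus not excluded, and the block may join unlike libraries. A block for the replicate numbers gave 3, 63, 2463, 1715, 0 and 75. It shared 2 of 3 calls at 3 weeks, where Nnt was lost (edgeR adjusted p 0.085), 44 of 64 at 8 weeks and 52 of 83 over both ages.

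Library totals gave 47 of 192 list medians the opposite sign, 11 of 32 for genotype at 8 weeks and 11 of 32 over both ages. The turned directions below are those of named genes and of lists by camera, and the cause was not tested. With library totals these were Kcne2 (-0.04), Sst (-0.08), Map1lc3b (-0.11), Lamp1 (-0.09), Ndufa1 (-0.04), Sdhb (-0.01), Ndufa4 (-0.06), Nr1d2 (-0.13) and Tef (-0.13) for age in wild type. By camera adjusted p they were the squamous (0.0011), lysosome (0.065) and oxidative phosphorylation (0.065) lists at 8 weeks, B and plasma cells for age in wild type (0.0077), lysosome for the interaction (0.53), and the squamous (0.0091) and oxidative phosphorylation (0.0091) lists over both ages. Leaving out 1 library turned the squamous list at 3 weeks (7.6e-05 without WT_3wk replicate 2), at 8 weeks (0.0012 without WT_8wk replicate 1), for age in knockout (0.014 without KO_3wk replicate 2) and for the interaction (0.016 without WT_3wk replicate 2). It also turned endoplasmic reticulum stress at 8 weeks (0.03) and for the interaction (0.00027) without WT_8wk replicate 1, hepatocytes for age in knockout (0.00011 without KO_3wk replicate 1) and enteric neurons for age in knockout (0.024 without KO_8wk replicate 1, 0.026 with both left out).

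For these lists the adjusted p without 1 library ran from 7.1e-05 to 0.75 (squamous, 3 weeks), 0.0012 to 0.95 (squamous, 8 weeks), 0.014 to 0.84 (squamous, age in knockout) and 0.006 to 0.89 (squamous, interaction). It ran from 4.9e-08 to 0.66 (endoplasmic reticulum stress, 8 weeks), 7.6e-07 to 0.96 (the same, interaction), 0.00011 to 0.92 (hepatocytes, age in knockout) and 0.024 to 0.96 (enteric neurons, age in knockout).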

Other observations

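Tissue neighbours of the glandular stomach varied between libraries of the same group. Squamous forestomach scores were 4.63 and -1.55 in WT_3wk, -1.84 and 4.98 in WT_8wk, 4.63 and -0.82 in KO_3wk and 1.71 and 2.83 in KO_8wk, and the list had no call for genotype at 3 weeks (median log2 fold change 0.10, camera adjusted p 0.71; adjusted p = 0.95 with an estimated correlation) or 8 weeks (-1.80, 0.96; adjusted p = 0.98 with an estimated correlation). The keratin gene Krt13 followed the squamous score. Enteric neuron and glia genes scored 3.07 in KO_8wk replicate 2 and at most 2.55 elsewhere, with no call at 8 weeks (median 0.36, 0.077; adjusted p = 0.74 with an estimated correlation). The mesothelium score was 1.90 in KO_8wk replicate 2 and 0.06 in KO_8wk replicate 1.

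The galectin list, which includes Lgals8, had no call for genotype at 3 weeks (median 0.10, camera adjusted p 0.71) or 8 weeks (0.29, 0.14; adjusted p = 0.53 with an estimated correlation), though 4 members were higher and Lgals8 lower at 8 weeks adjusted over the list alone. Intestinal epithelial genes had no call for age in wild type (0.25, 0.56) or knockout (0.57, 0.051), while Apoa1 rose in both, 2.66- and 2.56-fold (edgeR adjusted p 0.0030 and 0.0042), and Alpi fell 12.1-fold in wild type (0.029). Adipocyte genes had no call at 8 weeks (-0.11, 0.68). Among the 5 sex-linked genes, Ddx3y was 24.1 to 32.7 CPM in all libraries, and the list's median was -0.20 for genotype at 3 weeks and -0.18 at 8 weeks, 0.18 under library totals; it was not tested with camera.

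The genotype calls over both ages were weighed against strain differences and grouping, with both rules written before the result was seen. Called genes lay within 20 Mb of Lgals8 at 11.2 times the share of tested genes, which is consistent with a flanking segment of another strain carried with the null allele; an effect of Lgals8 on its neighbours was not tested. On the values given here, strain differences elsewhere stay open, as Nnt, which carries a deletion of several exons in C57BL/6J, lay at 141.2% to 225.4% of the wild-type mean of the same age in the 4 knockout libraries, and gene counts cannot tell the strain. By the same measure Mmrn1 (0%) and Wdfy1 (493.9% to 565.8%) are open in the same way. Ide (54.5% to 86.5%) and Fgfbp3 (34.8% to 73.2%) were lower, but the WT_3wk libraries stood apart most. Ide was at 103.07 and 126.55 CPM in WT_3wk, 59.23 and 66.06 in WT_8wk, and 52.5 to 69.31 in knockout. Fgfbp3 was at 4.38 and 4.4, 1.91 and 1.82, and 1.34 to 1.79 CPM. For both genes the cause was not tested. Of 18 within-age splits of the libraries, 1, the real one, gave 83 calls and the others 0, but 18 splits cannot reach a share under 0.05.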
